A study of Lissachatina fulica and Mizuhopecten yessoensis with 12 samples.

How the data were processed

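Atria and ventricles of adult scallop (Mizuhopecten yessoensis) and giant African snail (Lissachatina fulica) hearts were profiled by poly-A selected bulk RNA sequencing, with 3 libraries per chamber and species, 12 in all. Chamber, species and replicate number were taken from the sample titles. The labels do not say whether the replicates came from separate animals, or whether same-numbered atria and ventricles shared an animal, so p-values measure only the spread between these libraries, which may be partly technical. HISAT2 2.0.5, featureCounts 1.5.0, StringTie 1.3.3b and DESeq2 1.20.0 were named, with no role or order, per the submitters' processing notes. The genome builds, annotations and strand setting were not given in the sources used here, so overlapping genes and near-identical copies could share or split reads.

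One table per species was used. Its library columns held a signal that the authors deposited as normalized counts, that is gene read counts divided by 1 size factor per library. The values bear this out: in each of the 12 libraries 100% of values were whole multiples of 1 step, with a tolerance of 0.01 read, and the deposited mean column equalled the mean of the 6 libraries. No gene length entered these values, so abundance below means a high normalized count, not a number of transcripts. The authors' deposited log2 fold changes and their standard errors were for ventricle over atrium. The deposited test score was the fold change divided by its standard error, and the deposited p-values were given without and with adjustment. The tables listed only a selected part of the genes: every row had an unadjusted p under 0.05 and an absolute log2 fold change of at least 1.001 in the authors' deposited table. The authors' adjusted p-values imply that 17501 scallop genes and 13325 snail genes entered their adjustment, and that about 5263 (30.1%) and 2676 (20.1%) of them had p under 0.05 before any fold limit. Genes outside the tables were not used here. A test over the listed rows is therefore not independent evidence that a gene differed. Direction, size and spread are the results, and absence from a table says nothing about a gene's level.

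The scallop table had 4195 rows, of which 2490 carried a gene symbol (2228 different symbols) and 1705 only an identifier. The snail table had 1886 rows, 1042 with a symbol (862 different) and 844 without, counting as unnamed 2 rows whose symbol had been turned into a date. Symbols are annotation names taken from other animals and are not ortholog calls.

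The design named edgeR for counts and limma for counts divided by size factors, and the second case applied. Fold changes were computed here as atrium over ventricle with limma 3.58.1 (R 4.3.3), with a mean-variance trend, on log2(normalized count + 1), which understates the change of low genes. Rows with a mean of at least 10 over the 6 libraries were tested, 3927 in scallop and 1489 in snail; 268 and 397 rows lay below. A gene passed the threshold with a Benjamini-Hochberg adjusted p under 0.05 over the tested rows and at least a 2-fold change. Recovered whole reads were tested with edgeR 4.0.16 and DESeq2 1.42.0 as alternatives. On simulated counts, the limma test recovered 41% of 100 genes changed 4-fold in the scallop table and 39% in the snail table, and 1% of 100 genes changed 2-fold in each. It called 2 of 3727 and 3 of 1289 unchanged genes. Most simulated genes were unchanged, and the 2-fold limit was not applied to them. Every row of the real tables had been selected as different, so these rates do not describe the test as used.

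Gene lists were tested with camera at a preset inter-gene correlation of 0.01, 2-sided, where a list had at least 5 tested members, against the other tested rows of the same table. Every camera call was repeated with an estimated correlation, with fry and with Fisher's exact test of direction. The tests, the rule for named genes, the other settings to try and the themes of 18 lists were fixed before the data were examined. Their first patterns searched descriptions, which the tables lack, so symbol patterns for the same themes were written after the symbols, but not the directions of the members, had been read. The lists of mitochondrial ribosome, proteasome, fatty acid oxidation and developmental transcription factors (4 lists) were added after the symbols had been seen. Genes of both species were compared by identical symbol with a limma interaction of species and chamber over all 12 libraries, using the copy with the highest mean, and list directions were compared by Fisher's exact test where each species had at least 3 calls. The species term absorbs a constant difference in normalization between the tables, so only chamber differences, never levels, were compared between species. A scaling shift between the chambers within a species is not absorbed and would enter the interaction.

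Named genes were chosen by a rule fixed in advance. It took, per species and direction, the 6 symbols with the largest fold change among genes past the threshold whose chambers did not overlap and whose higher chamber had a mean of at least 100. It also took up to 2 abundant members in the main direction of each list, up to 6 cardiac transcription factors, and, between species, the 5 smallest interaction p-values per direction and the 5 largest changes shared in direction. Not every gene that the rule chose is named. Any other gene is named as chosen after its values were seen. Where a chamber had no read, the fold is a lower bound against a floor of 3 reads summed over the chamber's 3 libraries. Reads and size factors were summed over the chamber for these folds, so a fold can differ from the ratio of the mean level to the floor. Where a chamber had 1 to 3 reads, the ratio is given with an exact 95% binomial interval. Floors and intervals cover counting error only.

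Alternatives changed the pseudocount (0.5, 5), the filter (none, a mean of 50), the scaling (a further TMM scaling, quantile normalization), the tool, the threshold, the libraries (each left out in turn) and the use of the replicate number as a block. TMM scaling assumes that most genes do not differ, and quantile normalization that all libraries share 1 distribution. Neither need hold among genes selected as different, so a call lost under them does not show that a chamber difference is absent. A rescaling of the scallop libraries to equal medians of ribosomal protein genes was added after seeing the data, as were the scalings and the left-out libraries in the comparison of lists between species. Library depth is known only for listed genes. The size factors were 1.23, 1.05 and 1.35 for scallop atria, 0.904, 0.665 and 1.07 for scallop ventricles, 1.37, 1.32 and 1.50 for snail atria, and 0.926, 0.586 and 0.744 for snail ventricles. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).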

Results

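The atrium and the ventricle of adult scallop and giant African snail hearts were compared within each species, and the chamber differences were then compared between the bivalve and the gastropod. Each chamber of each species had 3 libraries. Reads on the listed genes numbered 11004967, 10120508 and 11987811 in the scallop atria and 21526834, 12841841 and 12860151 in the scallop ventricles. They numbered 1054839, 766181 and 1165104 in the snail atria and 741081, 680624 and 606309 in the snail ventricles. Total library sizes are unknown, because only genes that the authors had selected as different were listed. Levels below are normalized counts, given as mean ± SD with n = 3 libraries, and log2 fold changes are atrium over ventricle on the log2(normalized count + 1) scale, with their SE.

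In scallop hearts, genes of mitochondrial energy production were higher in the ventricle. All 70 listed members of the oxidative phosphorylation list passed the threshold with higher ventricular levels, at a median log2 fold change of −1.89 (camera adjusted p = 1.61e-15; adjusted p = 0.365 with an estimated correlation). ATP5B, a subunit of the mitochondrial ATP synthase, stood at 35580 ± 2220 in atria and 119100 ± 22600 in ventricles (n = 3), and SLC25A31, an ADP/ATP carrier, at 64060 ± 6060 and 178000 ± 47500. NDUFB2, a complex I subunit, showed the widest gap of the list, from 51.4 ± 32.8 to 1547 ± 720, a log2 fold change of −4.93 ± 0.56 (limma adjusted p = 0.000244). All 5 members of the glycolysis and phosphagen list were also higher in the ventricle (median −1.67, camera adjusted p = 0.021; adjusted p = 0.395 with an estimated correlation; Fisher's exact test of direction, adjusted p = 0.0886). Among them, GAPDH rose from 14940 ± 2010 in atria to 48080 ± 10800 in ventricles. Of 21 fatty acid oxidation genes, 20 were past the threshold toward the ventricle (13 without atrium 1 or without atrium 2) and none toward the atrium (median −1.47, camera adjusted p = 7.59e-05; adjusted p = 0.365 with an estimated correlation). ETFA, which passes electrons from fatty acid oxidation to the respiratory chain, stood at 1481 ± 70.9 and 4686 ± 1220. A further TMM scaling gave 58 oxidative phosphorylation and 7 fatty acid oxidation calls and quantile normalization 44 and 9, with no direction turned. A rescaling of the libraries to equal ribosomal medians gave 6 and 0 and turned 5 and 6 genes. The glycolysis and phosphagen list had 3 calls after the TMM scaling, 2 under quantile normalization and 0 after the rescaling. ATP5B, GAPDH, ETFA and SLC25A31 did not pass under quantile normalization or the ribosomal rescaling, nor SLC25A31 after the TMM scaling.

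Genes of protein synthesis, protein breakdown and the cell cycle lay on the same side. Of 63 cytosolic ribosomal protein genes, 60 were past the threshold toward the ventricle, within a narrow range (median −1.17, quartiles −1.26 and −1.11; camera adjusted p = 5.31e-08; adjusted p = 0.437 with an estimated correlation). Their direction turned in 9 of 63 genes under quantile normalization and in 45 under the ribosomal rescaling, and a further TMM scaling left 2 past the threshold. Mitochondrial ribosomal proteins had 59 of 63 genes toward the ventricle (median −1.49, camera adjusted p = 1.1e-09; adjusted p = 0.395 with an estimated correlation) and proteasome subunits 31 of 34 (median −1.32, camera adjusted p = 6.08e-06; adjusted p = 0.437 with an estimated correlation). A further TMM scaling left 31 and 5 of these, and the ribosomal rescaling turned the direction of 11 and 12. In the cell cycle list 57 genes were higher in the ventricle, 2 in the atrium and 5 did not pass (median −1.69, camera adjusted p = 2.47e-07; adjusted p = 0.403 with an estimated correlation). PCNA, the sliding clamp of DNA replication, stood at 402.6 ± 191 in atria and 2719 ± 1750 in ventricles, and MCM3, a part of the replicative helicase, at 547.8 ± 234 and 1435 ± 294. Of the stress and chaperone list 28 genes were higher in the ventricle and 6 in the atrium (median −1.24, camera adjusted p = 0.00218; adjusted p = 0.417 with an estimated correlation), among them the peroxiredoxin Prx5 at 20340 ± 650 and 56190 ± 8590. The TMM scaling gave 29 ventricular cell cycle calls and 8 stress calls and quantile normalization 55 and 12, while the ribosomal rescaling gave 1 and 0 and turned 15 and 11 genes. MCM3 and Prx5 did not pass under these 3 scalings, nor PCNA under the ribosomal rescaling, nor MCM3 without atrium 2 (limma adjusted p = 0.0509). Without atria 1, 2 and 3 in turn 17, 18 and 14 ribosomal protein genes passed, and without ventricles 1 and 2 in turn 23 and 28. Proteasome calls fell to 16, 20 and 19 without atrium 1, atrium 2 or ventricle 1, ventricular cell cycle calls to 29 and 34 without atrium 2 or ventricle 2, and ventricular stress calls to 13 without atrium 1. In ribosomal protein genes ventricle 3 lay 76.4% of the way from ventricles 1 and 2 toward the atrial mean, by the median. In oxidative phosphorylation genes it lay 48.2% of the way.

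In scallop, the neuronal, ion channel, developmental signalling and extracellular matrix lists were mostly higher in the atrium. In the neuronal list 50 genes were higher in the atrium, 7 in the ventricle and 2 did not pass (median 3.08, camera adjusted p = 3.1e-08; adjusted p = 0.193 with an estimated correlation). CCKAR, a cholecystokinin-type peptide receptor, stood at 572.2 ± 74 in atria with no read in any ventricle, at least 508-fold higher. AVPR1B, a vasopressin-type receptor, stood at 1873 ± 139 against 19.6 ± 19.7, and GRIN1, a glutamate receptor subunit, at 3930 ± 376 against 1495 ± 189. Of 26 ion channel genes 24 were higher in the atrium (median 2.23, camera adjusted p = 4.38e-05; adjusted p = 0.193 with an estimated correlation), and 15, 11 and 15 without atria 1, 2 and 3 in turn, led in abundance by UNC80, a regulator of a sodium leak channel, at 4133 ± 594 against 1837 ± 671. In the developmental signalling list 38 of 42 genes were higher in the atrium and 3 in the ventricle (median 1.98, camera adjusted p = 1.37e-08; adjusted p = 0.288 with an estimated correlation). WNT4, a secreted Wnt ligand, stood at 563.9 ± 138 in atria with no read in ventricles, at least 503-fold higher. SHH, a hedgehog ligand, had 1357 reads in atria and 2 in ventricles, a ratio of 493 after size factors (95% interval 136 to 4080). Of 54 extracellular matrix genes 47 were higher in the atrium and 4 in the ventricle (median 2.08, camera adjusted p = 7.97e-09; adjusted p = 0.193 with an estimated correlation). The fibrillar collagen COL1A2 stood at 148400 ± 14500 in atria and 53590 ± 33400 in ventricles, and the integrin subunit ITGB2 at 393.4 ± 145 and 1.48 ± 2.55. PTGER4, a prostaglandin receptor, had 1508 atrial reads against 3, a ratio of 365 (95% interval 125 to 1770). Quantile normalization gave 29 atrial calls in the neuronal list, 14 for ion channels, 33 for signalling and 40 for matrix, and turned 2, 0, 1 and 0 genes; the ribosomal rescaling turned 1, 1, 1 and 2. Without atrium 2, COL1A2 and UNC80 did not pass (limma adjusted p = 0.0531 and 0.0516).

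Among genes with a symbol that met the rule for named genes, the largest changes toward the scallop ventricle were in NKX3-2 and EPDR1. NKX3-2, a homeobox factor, stood at 4.78 ± 8.27 in atria and 232.0 ± 136 in ventricles, and EPDR1 at 4.91 ± 4.26 and 186.4 ± 76.1. RRM2B, a subunit of ribonucleotide reductase, rose from 109.0 ± 85.6 to 1301 ± 665, and LRP2, an endocytic receptor of absorptive epithelia, from 1423 ± 624 to 16150 ± 9780. SLC16A12, a carrier of the monocarboxylate transporter family, rose from 123.9 ± 61.4 to 1184 ± 188. These 5 genes and NDUFB2 had limma adjusted p-values from 0.000244 to 0.00421. Another EPDR1 copy, chosen after its values were seen, was past the threshold toward the atrium (log2 fold change 2.69).

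Contractile genes did not move as 1 group in scallop. In the sarcomere list 14 genes were higher in the ventricle, 6 in the atrium and 3 did not pass (median −1.03, camera adjusted p = 0.124). These counts depended on the scaling: 4 ventricular and 6 atrial calls after the TMM scaling, 2 and 5 under quantile normalization and 0 and 6 after the ribosomal rescaling. The direction turned in 1 of the 23 genes under quantile normalization and in 10 under the rescaling. Ventricular sarcomere calls fell to 6, 6 and 8 without atria 1, 2 and 3 in turn and to 9 without ventricle 2, and atrial calcium handling calls from 9 to 5 without atrium 2. The tropomyosin Tm2 stood at 190600 ± 3500 in atria and 481300 ± 125000 in ventricles (log2 fold change −1.30 ± 0.36, limma adjusted p = 0.0126). ACTB, an actin, stood at 466600 ± 77000 and 972400 ± 348000 (−1.01 ± 0.41, limma adjusted p = 0.0394), and its change went to 0 under quantile normalization and turned under the ribosomal rescaling. Quantile normalization gives a change of 0 to any gene that holds the same rank in every library, whatever its level, so this 0 says nothing about ACTB. Tm2 did not pass without any 1 of the atria (limma adjusted p from 0.0537 to 0.0609), or under any of the 3 scalings, and ACTB lost the call in 5 of 6 fits without 1 library. Of 14 calcium handling genes 9 were higher in the atrium and 5 in the ventricle (camera adjusted p = 0.268), with 9 and 2 calls after the TMM scaling, 4 and 1 under quantile normalization and 9 and 0 after the ribosomal rescaling, which turned 1 gene. The ryanodine receptor RYR2, a calcium release channel, stood at 7106 ± 727 in atria and 1865 ± 2410 in ventricles (2.90 ± 0.81, limma adjusted p = 0.0124, and 0.0512 without atrium 2). Its adjusted p in the authors' DESeq2 test was 0.0743. Ventricle 3 stood at 4632.9, and the log2 fold change of RYR2 was 4.05 without it and 1.97 without ventricle 2. A calmodulin copy, CALM3 (Miz0064710.1), stood at 322.9 ± 66 and 39.7 ± 32.6. A more abundant CALM3 copy (Miz0261910.1), chosen after its values were seen, was past the threshold toward the ventricle. It stood at 1992 ± 340 in atria and 6355 ± 1340 in ventricles (log2 fold change −1.66). The 6 listed cardiac transcription factors divided evenly (median −0.03 and mean 0.36, which differ in sign; camera adjusted p = 0.947). Both TBX20 copies, T-box factors of heart development, were higher in the ventricle, at 1546 ± 461 against 4694 ± 833 (limma adjusted p = 0.00408) and 1318 ± 393 against 4421 ± 1560 (limma adjusted p = 0.00481), and neither passed under the ribosomal rescaling. The Iroquois factor IRX4 was higher in the atrium, at 921.5 ± 546 against 123.8 ± 111 (3.12 ± 0.66, limma adjusted p = 0.00481), as were TBX10 at 173.0 ± 34.5 against 39.04 ± 34.5 and HES1 at 371.7 ± 65.1 against 179.6 ± 54. TBX2 lay at the edge of the threshold, at 129.5 ± 49.5 in atria and 292.3 ± 134 in ventricles (limma adjusted p = 0.0499), and its direction turned under the ribosomal rescaling. HES1 and TBX2 each lost the call in 4 of 6 fits without 1 library. Their adjusted p-values in the authors' DESeq2 test were 0.0534 and 0.0875.

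In the scallop hemocyte and immune list 29 genes were higher in the atrium, 12 in the ventricle and 7 did not pass (camera adjusted p = 0.021, with the list no longer called under the ribosomal rescaling, which turned 6 genes; adjusted p = 0.193 with an estimated correlation). The complement-type protein C5 stood at 14470 ± 1050 in atria and 3841 ± 315 in ventricles, and the multicopper oxidase Mco1 at 8233 ± 862 and 3204 ± 1150. In the ultrafiltration and excretion list 19 were higher in the atrium, 8 in the ventricle and 5 did not pass (camera adjusted p = 0.124), with CUBN, an endocytic receptor, at 3836 ± 471 against 700.5 ± 200. The hemocyte list had 31 and 2 calls after the TMM scaling, 19 and 9 under quantile normalization and 30 and 0 after the ribosomal rescaling. The excretion list had 21 and 4, 6 and 6, and 21 and 1 in the same order, and the cilia list 13 and 0, 7 and 5, and 13 and 0. Quantile normalization turned 1 excretion gene, and the rescaling 5 excretion and 4 cilia genes. Without atria 1, 2 and 3 and ventricle 1 in turn, atrial calls fell to 16, 12, 19 and 15 in the hemocyte list, 8, 7, 12 and 12 in the excretion list and 3, 4, 4 and 5 in the cilia list. The cilia list had 13 toward the atrium and 2 toward the ventricle (camera adjusted p = 0.11), the germline list 1 and 4 (camera adjusted p = 0.401), the oxygen transport list 1 and 3 (camera adjusted p = 0.216), and the epithelium and mucus list 2 and 0. These 3 small lists changed with the settings: germline had 1 or 2 ventricular calls without atrium 1, atrium 2, ventricle 1 or ventricle 2, oxygen transport had 5 without ventricle 3 and 1 after the TMM scaling or under quantile normalization, and epithelium and mucus had no call under quantile normalization. FTH1, an iron storage ferritin, stood at 11560 ± 1430 in atria and 33160 ± 17100 in ventricles, and did not pass without atrium 1 (limma adjusted p = 0.0534), without atrium 2 or under any of the 3 scalings. Among developmental transcription factors 22 were higher in the atrium and 8 in the ventricle (14 and 9 under quantile normalization; camera adjusted p = 0.0153; adjusted p = 0.193 with an estimated correlation), with SOX8 at 5251 ± 1540 against 1069 ± 507 and RUNX1 at 6976 ± 3940 against 2711 ± 1130. RUNX1 did not pass without atrium 2 or without ventricle 2 (limma adjusted p = 0.0883 and 0.0653).

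The authors' deposited table for scallop listed 2016 genes higher in the atrium and 2179 higher in the ventricle, of which 1190 and 1680 had the authors' adjusted p under 0.05. In the authors' deposited table, 686 genes exceeded an 8-fold change toward the atrium and 127 toward the ventricle. The limma test put 3440 of 3927 genes past the threshold, 1648 toward the atrium and 1792 toward the ventricle (47.9% atrial), and 1877 without atrium 1 and 1808 without atrium 2. Of the 3440 calls, 2727 also had the authors' adjusted p under 0.05. Adjusted over the list alone, the extracellular matrix list had 47 and 5 calls, the cell cycle list 2 and 58, the cilia list 12 and 2 and the oxygen transport list 1 and 5, and every other scallop list fixed in advance had the counts given above. The share of atrial calls depended on the scaling. It was 74.4% of 2324 calls after a further TMM scaling, which moved the median log2 fold change of all tested genes from −1.01 to −0.52. Quantile normalization gave 46.3% of 2106 calls and moved the median to −0.36. The ribosomal rescaling gave 96.7% of 1799 calls and moved it to 0.21. The assumptions of these scalings need not hold among genes selected as different.

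**Figure D1:**
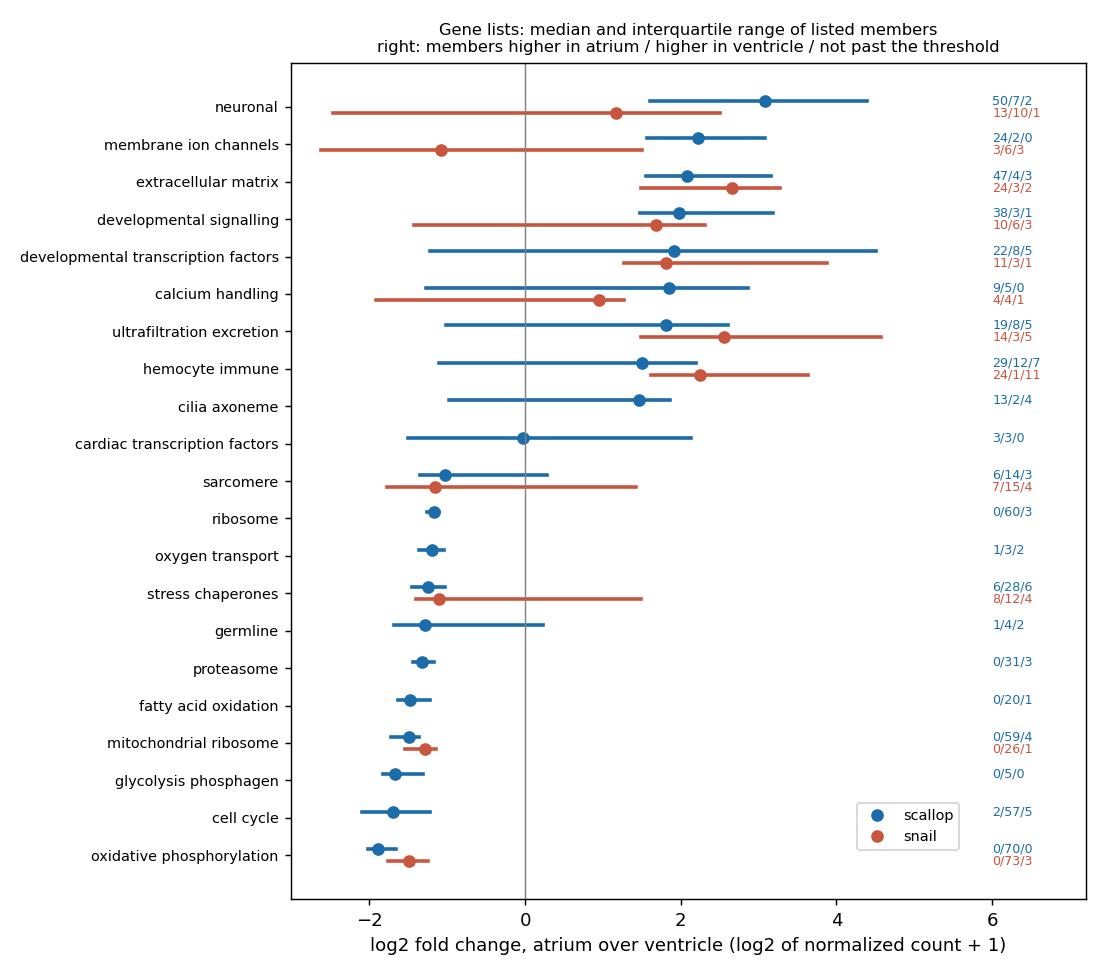
Median (point) and interquartile range (line) of the log2 fold change, atrium over ventricle, of the members of each gene list with at least 5 tested members, in scallop (blue) and snail (red), with the numbers of members higher in atrium, higher in ventricle and not past the threshold on the right. The oxidative phosphorylation list lay at −1.89 in scallop and −1.49 in snail, and the ion channel list at 2.23 in scallop and −1.07 in snail.

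In snail hearts, the oxidative phosphorylation list was again higher in the ventricle, with 73 of 76 genes past the threshold toward it and none toward the atrium (median −1.49, camera adjusted p = 3.45e-18; adjusted p = 0.499 with an estimated correlation). ATP5B stood at 6191 ± 389 in atria and 19380 ± 660 in ventricles, and SLC25A31 at 9165 ± 1420 and 29620 ± 8080, neither past the threshold under quantile normalization. Of 27 mitochondrial ribosomal proteins, 26 were higher in the ventricle (median −1.28, camera adjusted p = 9.48e-07; adjusted p = 0.499 with an estimated correlation), among them MRPL51 at 609.6 ± 110 and 2166 ± 807. All 4 listed glycolysis and phosphagen genes were higher in the ventricle, with 2 calls without ventricle 2. No cytosolic ribosomal protein was listed, and the proteasome and fatty acid oxidation lists had 1 member each, at −1.17 and −1.73. Of the stress and chaperone list 12 genes were higher in the ventricle and 8 in the atrium (median −1.10 and mean 0.04, which differ in sign; camera adjusted p = 0.283), 14 and 3 under quantile normalization, which turned 1 gene, and 7 and 6 without atrium 3. SOD2, a mitochondrial superoxide dismutase, stood at 426.5 ± 72.8 in atria and 1197 ± 185 in ventricles.

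Contractile genes of the snail leaned toward the ventricle, with 15 sarcomere genes higher there, 7 higher in the atrium and 4 not past the threshold (median −1.16, camera adjusted p = 0.0334; adjusted p = 0.499 with an estimated correlation). The myosin heavy chain gene unc-54 had the highest mean normalized count of the listed genes over the 6 libraries, though not in the atria alone. It stood at 85290 ± 9600 in atria and 234900 ± 81100 in ventricles (log2 fold change −1.41 ± 0.27, limma adjusted p = 0.00451). ACTB stood at 12620 ± 1280 and 49610 ± 32000, and neither unc-54 nor ACTB passed under quantile normalization. Calcium handling genes divided evenly, with 4 toward each chamber (median 0.95 and mean −0.03, which differ in sign; camera adjusted p = 0.729), but with 2 atrial and 4 ventricular calls under quantile normalization, which turned 2 genes, and without atrium 1. ATP2A2, the calcium pump of the sarcoplasmic reticulum, was higher in the atrium in 1 copy (Afu010007), at 769.7 ± 170 against 314.2 ± 26.2 (limma adjusted p = 0.00388). A more abundant copy, Afu011362, chosen after its values were seen, was higher in the ventricle, at 6623 ± 1740 against 24210 ± 2120 (limma adjusted p = 0.00111). TMEM38B, a potassium channel of the sarcoplasmic reticulum, stood at 27.7 ± 6.79 and 9.76 ± 3.39, a direction that turned under quantile normalization, and did not pass without atrium 1 (limma adjusted p = 0.0577). Its adjusted p in the authors' DESeq2 test was 0.0712. Of 12 ion channel genes 6 were higher in the ventricle and 3 in the atrium (median −1.07, camera adjusted p = 0.283), 7 and 0 under quantile normalization, and 3 and 3 without ventricle 2. Over all 18 listed members, 10 were higher in the atrium and 8 in the ventricle. HCN3, a hyperpolarization-activated channel of the pacemaker family, stood at 47.7 ± 6.24 in atria and 303.7 ± 53.9 in ventricles (−2.64 ± 0.25, limma adjusted p = 0.000615), and the potassium channel subunit KCNAB2 at 139.4 ± 26.1 and 316.0 ± 122, a change under 2-fold without ventricle 2 (log2 fold change −0.83).

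Of the 4 tested cardiac transcription factors of the snail, 3 were higher in the atrium and 1 in the ventricle. HAND2, a basic helix-loop-helix factor of heart development, had no read in any atrium and 293.4 ± 88.2 in ventricles, at least 426-fold higher there. HEY1 was higher in the atrium, at 84.4 ± 12.4 against 4.46 ± 1.96 (4.01 ± 0.39, limma adjusted p = 0.000615), as were GATA6 at 376.1 ± 27.6 against 162.9 ± 40.5 (limma adjusted p = 0.00563) and HES1 at 470.3 ± 88.4 against 220.5 ± 25.5 (limma adjusted p = 0.00626; under 2-fold without atrium 1, at a log2 fold change of 0.93). The nuclear receptor gene svp lay below the filter, at 10.6 ± 4.09 and 2.15 ± 2.84. With 4 tested members, this list was too small for camera. Of the developmental transcription factors 11 were higher in the atrium and 3 in the ventricle (camera adjusted p = 0.126), and 4 and 3 under quantile normalization, which turned 2 genes. They include TCF21, a factor of epicardial and kidney development in vertebrates, at 107.0 ± 20 against 2.67 ± 1.15, and OSR1 at 90.4 ± 5.48 against 31.9 ± 28.7, which lost the call in 4 of 6 fits without 1 library and under quantile normalization. BMP10, a bone morphogenetic protein, had 1 copy (Afu015655) at 84.2 ± 30.4 in atria and 3010 ± 1650 in ventricles (−5.06 ± 0.46, limma adjusted p = 0.000499) and another (Afu004624) at 3454 ± 208 and 749.0 ± 221 (2.24 ± 0.26, limma adjusted p = 0.000869). The developmental signalling list had 10 genes toward the atrium and 6 toward the ventricle (camera adjusted p = 0.674), 7 and 8 under quantile normalization, with the protease BMP1 at 2328 ± 242 against 573.1 ± 102.

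Further ventricular genes of the snail included SLC17A5, a lysosomal sialic acid carrier, at 10.3 ± 6.07 in atria and 1496 ± 768 in ventricles. PCSK2, a prohormone convertase, stood at 11.7 ± 5.64 and 388.7 ± 103, and REM1, a GTPase that inhibits calcium channels, at 23.1 ± 12.4 and 521.9 ± 81. The related convertase PCSK1 lay on the other side, at 608.6 ± 122 in atria and 29.8 ± 8.83 in ventricles, as did the cholinesterase BCHE at 1094 ± 272 and 59.1 ± 25.9. Across the neuronal list 13 genes were higher in the atrium and 10 in the ventricle (camera adjusted p = 0.84), and 6 and 10 under quantile normalization, which turned 1 gene.

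The extracellular matrix, hemocyte and excretion lists of the snail were mostly higher in the atrium. In the extracellular matrix list 24 of 29 genes were higher in the atrium and 3 in the ventricle (median 2.65, camera adjusted p = 0.00152; adjusted p = 0.499 with an estimated correlation). THSD4, a thrombospondin-repeat protein, stood at 8254 ± 2240 in atria and 79.02 ± 76.7 in ventricles (7.23 ± 0.79, limma adjusted p = 0.000795), FRAS1, a basement membrane protein, at 2408 ± 939 and 21.4 ± 23.7, and the collagen COL5A2 at 11030 ± 4070 and 4872 ± 1640, which lost the call in 4 of 6 fits without 1 library. CPVL, a serine carboxypeptidase, had the largest fitted change on the log2(normalized count + 1) scale, from 15.8 ± 19.2 in ventricles to 7264 ± 981 in atria (9.44 ± 0.79, limma adjusted p = 0.000463), and CRIM1, a membrane protein that binds growth factors, stood at 178.0 ± 74.9 and 1.80 ± 3.12. In the hemocyte and immune list 24 genes were higher in the atrium, 1 in the ventricle and 11 did not pass (median 2.25, camera adjusted p = 0.000915; adjusted p = 0.499 with an estimated correlation). CD109, a thioester protein, stood at 1925 ± 1400 in atria and 44.2 ± 22.8 in ventricles. In the ultrafiltration and excretion list 14 were higher in the atrium, 3 in the ventricle and 5 did not pass (median 2.56, camera adjusted p = 0.0562; 0.0134 without atrium 2). Quantile normalization gave 18 atrial and 3 ventricular calls in the matrix list, 12 and 1 in the hemocyte list and 12 and 4 in the excretion list, and turned 2, 1 and 0 genes. MMEL1, a neprilysin-type peptidase, stood at 1776 ± 857 against 263.8 ± 52.9.

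Atrium 2 of the snail stood apart in part of these genes. Of 858 tested genes higher in the atrium, 159 (18.5%) lay in atrium 2 below 10% of the mean of atria 1 and 3, against 3 genes for atrium 1 and 0 for atrium 3 measured in the same way. Cda5, a chitin deacetylase, stood at 22954 and 16811 in atria 1 and 3, at 345 in atrium 2 and at 50.2 ± 39.9 in ventricles (limma adjusted p = 0.00914). FIBCD1, a fibrinogen-domain chitin receptor, stood at 716, 3.03 and 3369.6 in atria 1, 2 and 3 with no read in ventricles, an atrial sum at least 1090-fold higher, and at least 275-fold without atrium 3, and lost the limma call in 4 of 6 fits without 1 library. The 159 genes held 13 of the 35 atrium-higher members of the hemocyte and immune list and 8 of the 18 of the excretion list. The correlation across genes of atrium 2 with the other atria averaged 0.702, and with the ventricles 0.661, over genes that are not independent replicates. Atria 1 and 3 averaged 0.485 and 0.340 with the ventricles, so atrium 2 lay nearer to them.

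**Figure D2:**
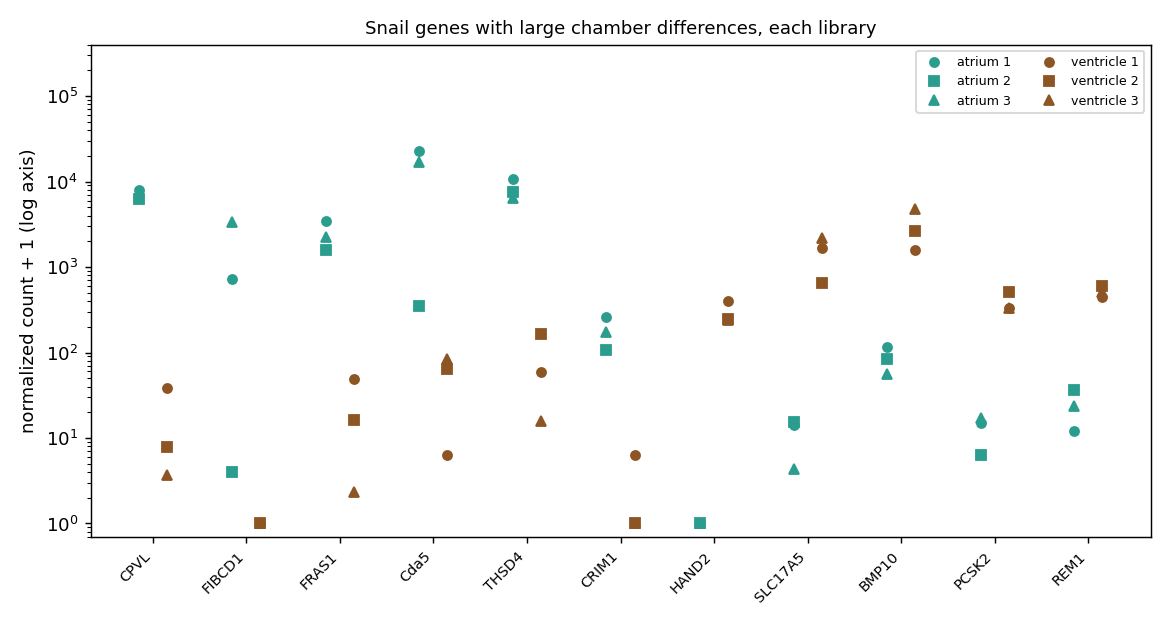
Normalized count + 1 on a log axis in each of the 6 snail libraries (circles, squares and triangles for replicates 1, 2 and 3, green for atria, brown for ventricles). The genes are those with a symbol that the rule for named genes took for large changes, 6 toward the atrium and 5 toward the ventricle. Genes without a symbol were not drawn. FIBCD1 and Cda5 were low in atrium 2, while CPVL ranged from 6174 to 8074 over the 3 atria.

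The remaining snail lists were small. The cell cycle list had 3 genes toward the atrium and none toward the ventricle. Quantile normalization turned 2 of these 3 genes and left 1 call, and 1 call passed without atrium 1, atrium 3 or ventricle 3. The oxygen transport and the epithelium and mucus lists had 1 gene each toward the atrium, the germline list 1 toward each chamber, and the cilia list 1 toward the ventricle. The epithelium, atrial germline and cilia calls were lost in 5, 5 and 4 of 6 fits without 1 library. The authors' deposited table for snail listed 1184 genes higher in the atrium and 702 higher in the ventricle, of which 733 and 539 had the authors' adjusted p under 0.05. In the authors' deposited table, 603 exceeded an 8-fold change toward the atrium and 91 toward the ventricle. The limma test put 1249 of 1489 genes past the threshold, 698 toward the atrium and 551 toward the ventricle (55.9% atrial). Of the 1249 calls, 1084 also had the authors' adjusted p under 0.05. Among the 825 genes with a mean of at least 50, 323 passed toward the atrium and 397 toward the ventricle (44.9% atrial, median log2 fold change −0.97 against 1.22 over all tested genes). Adjusted over the list alone, the hemocyte and immune list had 22 and 1 calls, the sarcomere list 7 and 16, the oxidative phosphorylation list 0 and 74 and the developmental signalling list 10 and 7, and every other snail list fixed in advance had the counts given above. Quantile normalization gave 905 calls, 34.5% of them atrial, and moved the median log2 fold change of all tested genes from 1.22 to 0.23.

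Between the species, 382 symbols were shared by both tables, 328 of them by tested genes. The same chamber was higher in both species for 260 of the 328 (79.3%), 182 in the ventricle and 78 in the atrium (Fisher's exact test, 2-sided, p = 2.23e-22, odds ratio 12.3, 95% interval 6.96 to 22.4, across genes, which are not independent replicates). Only symbols that the authors had selected as different in both species could be counted. Every listed oxidative phosphorylation and mitochondrial ribosome gene was ventricular in both species, and those with a shared symbol add to the 182. THSD4 was higher in the atrium in both, at log2 fold changes of 4.88 in scallop and 7.23 in snail. MEP1B, a meprin metalloprotease, stood at 4.33 and 4.71, and the peptide receptor QRFPR had 402 atrial reads against 2 in scallop (95% interval of the ratio 40.2 to 1210) and a snail log2 fold change of 3.75. GRIN2B, a glutamate receptor subunit, stood at 4.29 in scallop and at least 19.2-fold higher in snail atria, with no read in snail ventricles. SULP-6, a sulfate permease, stood at 2.70 in scallop. Its snail copy stood at 104.7 ± 135 in atria, with no read in atrium 2, and did not pass (limma adjusted p = 0.0789). On 1 ventricular read its ratio was 250 (95% counting interval 44.7 to 9900), and 66.3 without atrium 3. The interaction of species and chamber was past the threshold for 77 symbols (limma adjusted p under 0.05), 63 of which went in opposite directions. Neither the interactions nor the shared directions were repeated under the other scalings, so their dependence on a scaling shift between chambers is unknown. MMEL1 was higher in the ventricle in scallop, at 1101 ± 263 in atria against 4371 ± 1230, and in the atrium in snail (interaction adjusted p = 8.92e-06). PTGER4 in a scallop copy other than that named above, the retinal dehydrogenase ALDH1A1, BCHE and the glutamate dehydrogenase GLUD1 also went toward the ventricle in scallop and the atrium in snail. ARHGAP21 went the other way, at 4651 ± 263 in atria against 1612 ± 135 in ventricles of scallop and 147.5 ± 8.98 against 543.2 ± 135 in snail (interaction adjusted p = 8.92e-06). SLC17A5, the receptor GPRNNA1 and the sulfatase SULF1 had the same pattern.

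**Figure D3:**
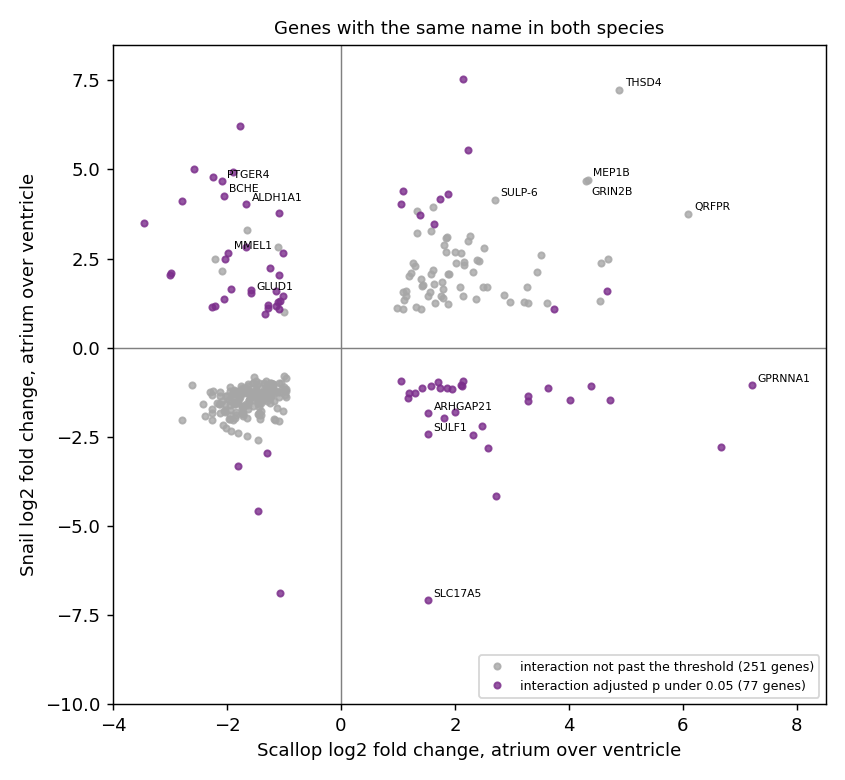
Log2 fold change, atrium over ventricle, of the 328 symbols shared by tested genes of both tables, in scallop (horizontal axis) and snail (vertical axis); purple points are the 77 symbols with an interaction adjusted p under 0.05. The lower left quadrant holds 182 symbols and the upper right 78.

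The share of atrial calls also differed between the species in 5 lists. These tests count genes, which are not independent replicates, so their p-values do not measure the spread between libraries. Over all calls, 47.9% were atrial in scallop and 55.9% in snail. Ion channel calls were atrial for 24 of 26 scallop genes (92.3%) and 3 of 9 snail genes (33.3%; Fisher's exact test, adjusted p = 0.009). Neuronal calls were atrial for 50 of 57 and 13 of 23 (adjusted p = 0.0245), developmental signalling calls for 38 of 41 and 10 of 16 (adjusted p = 0.0372), hemocyte and immune calls for 29 of 41 and 24 of 25 (adjusted p = 0.0372), and cell cycle calls for 2 of 59 and 3 of 3 (adjusted p = 0.00397). Over all listed members the hemocyte and neuronal differences no longer passed (adjusted p = 0.0848 for each). The hemocyte difference did not pass after the TMM scaling (31 of 33 and 26 of 26; adjusted p = 0.935), under quantile normalization (0.334), after the ribosomal rescaling of scallop (0.591), or in 9 of 12 fits without 1 library. The cell cycle difference did not pass after that rescaling, with 2 of 3 scallop calls atrial, and had too few snail calls to be compared under quantile normalization and in 4 of 12 fits without 1 library. Over all listed members ion channel genes were atrial in majority in both species (93.3% and 55.6%, adjusted p = 0.0226). The ion channel, neuronal and signalling differences passed under all 3 scalings, but not in 2, 1 and 6 of the 12 fits without 1 library. The other 10 lists compared, among them oxidative phosphorylation and extracellular matrix, gave adjusted p-values from 0.27 to 1. Members of a list differ between the species, and a symbol shared by both is not an ortholog call.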

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

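The tests of the 3 patterns weighed here were chosen after the values had been seen; the splits of the libraries were planned.

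Of the 328 symbols shared by tested genes, 77 stood out because a test of the difference itself showed unlike chamber differences in scallop and snail. Among the named ones, the snail minus scallop difference in log2 fold change was 4.64 for MMEL1, 6.77 for PTGER4, 5.69 for ALDH1A1, 6.31 for BCHE and 3.11 for GLUD1. It was −3.37 for ARHGAP21, −8.61 for SLC17A5, −3.96 for SULF1 and −5.81 for 1 further symbol. The fitted −8.27 for GPRNNA1 is no size, because that gene had no read in scallop ventricles; the atrial level was at least 129-fold higher there. Lists stood out in Fisher's exact test between species for ion channels (adjusted p = 0.009), hemocyte and immune genes (0.0372), neuronal genes (0.0245), developmental signalling (0.0372) and the cell cycle (0.00397). Genes counted in that test are not independent replicates. Copies that share a symbol need not be orthologs. For PTGER4, 2 other scallop copies were past the threshold toward the atrium, the chamber that was higher in snail. The snail cell cycle list had only 3 calls, and the hemocyte difference passed under none of the 3 other scalings.

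The 6 scallop libraries gave 3440 genes in the real grouping and at most 3 in any other split, so 1 of the 10 splits was as large. The 6 snail libraries gave 1249 and at most 1, again 1 of 10. With 10 splits no share under 0.05 can be reached, and the genes had been selected on the real grouping.

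The first pattern is the low level of 159 atrium-higher genes in snail atrium 2. Ventricular tissue in that sample as the whole cause is argued against for the listed genes. Ventricle-higher genes had a median log2 ratio of atrium 2 to the other atria of 0.0293. A smaller amount of ventricular tissue stays open, because the authors' selection included atrium 2 and can leave out genes raised there. Lower depth is argued against as well, since the size factor was 91.8% of the mean of atria 1 and 3. A hypothesis is that atria 1 and 3 may have carried excretory tissue: list members made up 5.03% of the low genes and 1.43% of the others (Fisher's exact test, 2-sided, p = 0.00955; adjusted p = 0.0478 over 10 lists), with SLC34A2, a phosphate carrier chosen like LRP2 after its values were seen, at 304, 19.7 and 628 in atria 1, 2 and 3, and LRP2, which did not pass (limma adjusted p = 0.0745), at 91.2, 3.79 and 397. The hemocyte list was enriched too (Fisher's exact test, 2-sided, p = 0.00702; adjusted p = 0.0478), so the markers single out no 1 tissue. The log2 ratio of atrium 3 to atrium 1 had a median of 1.51 in the low genes and 0.0864 in the others, which 1 source of fixed makeup could give, but spread 1.88 times as widely in the low genes; that source, other extra tissue and a difference between animals cannot be told apart here, since no library of another tissue was used.

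The second pattern is that ribosomal, proteasomal and mitochondrial genes were all higher in scallop ventricles. The median log2 fold change of oxidative phosphorylation differed from that of ribosomal proteins by −0.714. The same difference taken within each library separated atria from ventricles with a Welch test p of 0.0518 on log2 levels and 0.011 on log2 levels centred per gene, so with 3 libraries per chamber a scaling shift as the whole cause is left open. For the 63 ribosomal protein genes themselves, a scaling shift and a higher ventricular level cannot be told apart, because genes outside the table were not used.

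The third pattern is scallop ventricle 3, which lay nearer to the atria in ribosomal genes. Atrial tissue as the whole cause is argued against for the listed genes. There were 567 genes at least 8-fold higher in the atria than in ventricles 1 and 2. Their median share of the way to the atrial mean was 6.55% (quartiles 0 and 30.7%). That is 8.58% of the share in ribosomal genes (76.4%, quartiles 73.1% and 80.1%). A smaller amount of atrial tissue stays open, because the authors' selection included ventricle 3 and can leave out genes raised there. Across genes, ventricle 3 correlated with the atria at a mean of 0.795, against 0.752 and 0.741 for ventricles 1 and 2. A scaling error in the ventricle 3 library stays open. Its log2 ratio to ventricles 1 and 2 differed between oxidative phosphorylation and ribosomal genes by 0.315. Atrium 3 against the other atria gave 0.345. A difference between animals stays open and untested.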

How the results depend on the processing

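The rescaling to equal ribosomal medians, and the scalings and left-out libraries in the comparison of lists between species, were chosen after seeing the data; all other alternatives were planned. Against 3440 scallop calls, quantile normalization gave 2106 (1928 of them shared, with 39 of the 3440 turned), the ribosomal rescaling 1799 (1698 shared, 530 turned) and an adjusted p under 0.01 left 1111, and leaving out 1 library gave 1808 to 3483, the lowest without atrium 2 and 1877 without atrium 1. Against 1249 snail calls, a mean of at least 50 gave 720, 716 of them shared, fewer genes being tested, an adjusted p under 0.01 left 716, and leaving out 1 library gave 961 to 1282. All other alternatives stayed within 1.5 times. Of the list calls, 14 in scallop and 5 in snail, 0 and 0 held with an estimated correlation, and fry gave 19 and 10. Unlike camera, fry tests the members of a list alone, not against the other tested rows. Every row had been selected as different, so the fry calls are no independent support. Leaving out 1 library gave 14 to 14 and 5 to 6 camera calls. Symbols that occur once in each table gave 45 interactions in place of 77, among 241 symbols, and leaving out 1 library gave 68 to 90, with 260 to 261 symbols going the same way. The authors had selected the genes on these same libraries, so directions could hardly turn without 1 library, and that narrow range is no support. The 3 scalings were not run on the shared symbols. Of 5 lists different between species, counting all listed members left 3 past the threshold; leaving out 1 library gave 1 to 4, the lowest without snail ventricle 1, the TMM scaling 4 and quantile normalization 3. The rescaling left 3, without the hemocyte and cell cycle lists. By its construction, it reversed the scallop minus snail difference in percent atrial calls for sarcomere (68.2) and stress genes (60), which then passed, and for hemocyte genes (4), which did not; among lists that differed under neither, the sign also turned for excretion and for cardiac and developmental transcription factors.

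Quantile normalization brought scallop Miz0185270.1 ACTB to 2.24e-15, 0 but for rounding, and reversed RPL7A (0.15) and snail TMEM38B (−0.028), none past the threshold after it. By its construction, it gives a change of 0 to any gene that holds the same rank in every library. The ribosomal rescaling reversed ACTB (0.21), RPL7A (0.10), P4HB (0.088), PSMC1 (0.19), HADHB (0.058) and TBX2 (0.080), by its construction. It left 6 ventricular oxidative phosphorylation calls, 1 for the cell cycle and 1 in the excretion list. A further TMM scaling ended the calls of 15 named scallop genes, quantile normalization 18, and 8 in snail, and the rescaling 26, reversed ones included; the cause was not tested. These include Tm2, SLC25A31, FTH1, MCM3 and Prx5, all ventricular. The edgeR test ended those of TTYH2, TBX2 and OSR1. In the authors' DESeq2 test TTYH2 had an adjusted p of 0.162. Of 106 named genes with a test, 30 lost the call without at least 1 library. ACTB, PSMC1, IFT172, TTYH2, P4HB and RPL7A lost it in 5 of 6 such fits, and FIBCD1 and snail COL5A2 in 4. The fitted fold of 22 of 104 named genes past the threshold moved by over 1.5 times without 1 library, 0 of them changing direction. The farthest log2 values were 8.55 for ITGB2 and 6.02 for AVPR1B (without ventricle 1), −7.72 for NKX3-2, −4.41 for EPDR1 and −2.95 for RRM2B (atrium 2), 4.05 for RYR2, 2.16 for TTYH2 and 3.16 for TBX10 (ventricle 3), 2.65 for CALM3 (ventricle 1) and 3.81 for IRX4 (ventricle 2) in scallop. In snail they were 10.4 for CPVL and 7.40 for CRIM1 (ventricle 1), 2.49 for OSR1 and 3.22 for REM1 copy Afu012335 (ventricle 2), 6.34 for FRAS1, 6.35 for THSD4 and 7.52 for Afu012226 (ventricle 3), 10.6 for FIBCD1, 9.24 for Cda5, 7.28 for SLC34A2 and 6.37 for CA14 (atrium 2) and −6.50 for SLC17A5 (atrium 3).

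With the replicate number as a block, 3022 scallop and 1170 snail genes passed, and 14 and 6 lists; the added snail list was excretion (adjusted p = 0.0486). Deviations from the chamber mean correlated between same-numbered libraries at −0.129, −0.165 and −0.116 in scallop and −0.059, −0.0915 and 0.0586 in snail, so the numbers were not taken as pairs. No atrium correlated best with the ventricle of its own number, and of the ventricles only snail ventricle 3 did so with its atrium. HES1, IFT172 and TBX2 of scallop lost their call under the block. Only listed genes have a known depth, so library-wide sampling error is open.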

Other observations

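The genes in this part were chosen after their values were seen. Some symbols had copies on opposite sides. Of 78 snail symbols with at least 2 copies past the threshold, 15 (19.2%) had copies in both directions, and of 144 scallop symbols 28 (19.4%). Mlc1, a myosin light chain, had a snail copy (Afu021142) at 2704 ± 599 in atria and 281.4 ± 71 in ventricles (SD, n = 3; log2 fold change 3.26, limma adjusted p = 0.00049) and another (Afu017761) at 723.9 ± 401 and 6625 ± 595 (−3.32, limma adjusted p = 0.000805). In scallop the Mlc1 copy Miz0054550.1 was higher in the ventricle, at 50410 ± 9010 and 180500 ± 59100, without passing under quantile normalization or the ribosomal rescaling. REM1 had 3 snail copies higher in the atrium (3.83 to 4.46), among them Afu012335 at 331.5 ± 42.1 against 23.6 ± 19.1, and 2 higher in the ventricle. The glycine receptor symbol GLRA3 had 2 scallop copies on each side, and the endocytic receptor LRP2 1 on each side. Reads shared between near-identical copies were not examined here.

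Some gene families moved together. CPVL had 11 listed copies in snail, and all 8 tested copies were past the threshold toward the atrium, at log2 fold changes of 3.03 to 9.44. GIMAP7, an immune-associated GTPase, had 4 snail copies toward the atrium. In scallop all 4 listed copies of TMEM173, the innate immune adaptor STING, were atrial. All 8 listed copies of HDLBP, an RNA-binding protein, and all 4 of the mitotic kinase AURKA were ventricular. Scallop GIMAP7 had 1 copy past the threshold on each side. Copies that did not differ would not be listed, and reads shared between near-identical copies were not examined. The ribosomal rescaling turned 1 copy each of HDLBP and AURKA, and no listed copy of CPVL, GIMAP7, TMEM173, HDLBP or AURKA turned under the TMM scaling or quantile normalization. The snail gene Afu012226, with no symbol, was among the listed genes with the highest normalized counts, at 105900 ± 37100 in atria and 467.5 ± 506 in ventricles (limma adjusted p = 0.00072).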
